A study of Homo sapiens with 5 samples.

How the data were processed

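Whole-cell small RNA was sequenced from HMLE cells (2 libraries) and from the mesenchymal subline mesHMLE (3 libraries). Per the labels' protocols, total RNA was extracted with Trizol, and libraries were made with a QIAseq miRNA kit, amplified and size-selected on a gel. HMLE was grown in serum-free epithelial medium. The subline was cultured in a different medium containing bovine serum and TGF-β1, and was afterwards kept in that medium without TGF-β1. When the libraries were taken relative to that withdrawal is not given in the sources used here.

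The authors deposited 1 file per library with raw counts, whole numbers with no normalization, for 2104 entries. Each entry is a miRBase accession of a mature miRNA with a suffix that numbers its loci. The submitters' processing notes list bcl2fastq, cutadapt 2.8, UMI-tools, BWA 0.7.17, edgeR 3.34.0 and the human genome build hg19, and the deposited file names carry the words for trimming, bwa, hg19 and deduplication. Where duplicates are removed by molecular identifier, a count stands for a tagged molecule more nearly than for a read. The counting program, its mapping quality minimum, its use of strand and the miRBase release are not given in the sources used here. Each file ends with rows for reads given to no entry, which were left out of library sizes and tests. Reads in no entry made up 33.98% and 41.7% of HMLE files and 18.3% to 20.95% of mesHMLE files. Reads under the mapping quality minimum made up 36.78% and 39.82% of HMLE files and 42.04% to 45.72% of mesHMLE files. Reads of ambiguous assignment were at most 0.00485%. Reads from mature sequences that occur at several loci may be set aside or split between loci by such counting, so the 144 accessions with several loci are uncertain.

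Assigned counts were 2558798 and 2751183 in HMLE replicates 1 and 5, and 2041847, 2321205 and 1777253 in mesHMLE replicates 3, 4 and 5. Groups and replicate numbers came from the sample titles. The 2 groups share only the replicate number 5, so that no replicate block was fitted.

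Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults left 582 entries, followed by TMM scaling (factors 0.917 to 1.115), estimateDisp (biological coefficient of variation 0.51), a robust glmQLFit and glmQLFTest for mesHMLE minus HMLE, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are on TMM-scaled library sizes. The SE of a log2 fold change is its size divided by the square root of the F statistic. Where a group had no counts, the fold was computed against 3 counts over the libraries of that group. It is a lower bound for counting error in that group only, with the mean of the other group taken as exact. In the counts of entries by size of change, the medians and the plot of fold change by abundance, groups with 1 or 2 counts were also set at 3 counts, a choice made after the values were seen. Measures of whole libraries were compared with exact permutation tests over the 10 ways of choosing 2 of 5 libraries, which cannot go below p = 0.1. The fit was tested on simulated data: in 20 simulations of the 582 entries for this comparison, with 200 entries changed, it recovered 63.2% of 4-fold and 95% of 16-fold changes, and 3.42% of all calls were false. The simulated entries varied independently of each other, so these rates do not cover entries that move together between libraries. As many entries were raised as lowered, so the rates also do not cover errors of scaling where most changes go in the same direction.

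The design, the tests and the alternatives were fixed before the data were examined. Alternatives were other scalings (RLE, upper quartile, library totals, and scaling without the 10 most abundant entries), other filters (none, or at least 10 CPM in at least 2 libraries), loci of 1 accession summed, each library left out, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit that was not robust, a threshold of 0.01, and glmTreat against a log2 fold change of 1. In the fits that left out libraries, the 582 tested entries were held fixed, and an arm left with 1 library was assumed to vary like the other.

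Tests of 20 preset lists of miRNAs and of the usage of the 5p and 3p arms had been planned. They were not run, because the accessions were not paired with names: 0 of the 1919 accessions were found in the gene table that was used. Its assembly is also not hg19, and no coordinates are given. The rule for named entries listed the 10 with the largest log2 fold change in each direction among those with adjusted p under 0.05, a mean of at least 10 CPM and no overlap between groups, together with the 5 most abundant entries of each group and members of named families. Since names were not used here, only 2 accessions in each direction are printed, the one with the largest fitted log2 fold change and the most abundant other one among those 10, a reduction made after the values were seen. The fitted value that ranked MIMAT0009197_1 first depends on the prior count, since all mesHMLE libraries are at 0. Another of the 10, with a fitted log2 fold change of -9.99, also had fewer than 3 counts over the mesHMLE libraries. With mesHMLE set at 3 counts for both, MIMAT0009197_1 at -8.19 lies behind that entry at -9.625.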

Results

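Small RNA libraries were compared between HMLE cells, an immortalised human mammary epithelial cell line, and mesHMLE, a subline of the same cells with a mesenchymal phenotype. The subline was derived by treatment with TGF-β1, the growth factor that drives epithelial to mesenchymal transition in many epithelial cells. There were 2 HMLE libraries (replicates 1 and 5) and 3 mesHMLE libraries (replicates 3, 4 and 5), the latter labelled with 2.5 ng/ml TGF-β for 18 days. The comparison asks how the miRNA profile of whole cells differs between the epithelial and the mesenchymal state. The groups also differed in culture medium, since mesHMLE was grown with serum and HMLE without, so that TGF-β exposure and medium could not be told apart. The labels do not say whether replicates were separate cultures, and the p-values below measure the spread between these libraries, which may be technical. Entries are miRBase accessions of mature miRNAs with a locus suffix. The sources used here do not pair them with miRNA names, arms or genomic positions, and no miRNA family is named.

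The libraries held between 1777253 and 2751183 deduplicated reads assigned to miRNA entries. A single count was therefore worth less than 1 CPM (the count scaled to the library size) in each, and a count of 0 allowed a level of up to between 1.09 and 1.69 CPM, for counting error only. Of 2104 entries, 1203 had a count in any library and 901 had none. Counts were concentrated in few entries. The 10 most abundant held 44.8% ± 0.0314 (SD, n = 2) of assigned counts in HMLE and 48.0% ± 2.35 (SD, n = 3) in mesHMLE. The difference was 3.22 percentage points (exact two-sided permutation test, p = 0.2, adjusted p = 0.229 over 8 library measures, smallest possible p 0.1). The groups did not overlap in this share (44.77% to 44.81% and 46.36% to 50.7%), but another arrangement of the libraries gave a difference at least as large. The most abundant entry, the same in both groups, stood at 128110 ± 14040 CPM in HMLE (SD, n = 2) and 131340 ± 14600 CPM in mesHMLE (SD, n = 3), after TMM scaling. As an unscaled share of assigned counts it held 11.75% ± 1.26 (SD, n = 2) and 13.85% ± 0.702 (SD, n = 3). These shares did not overlap between the groups (exact two-sided permutation test, p = 0.1, adjusted p = 0.2). Of the 7 entries among the top 5 of either group, 3 were in both lists and 1 differed between the groups by edgeR's quasi-likelihood test.

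The entries that distinguished mesHMLE from HMLE mostly fell, and some fell almost to nothing. Of 582 entries tested, 72 were lower and 31 higher in mesHMLE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 479 did not pass. Among the called entries the losses were deeper than the gains. Among the entries that fell, 55 did so by at least 4-fold, 20 by at least 16-fold and 14 by at least 64-fold, whereas 15 entries rose by at least 4-fold and 0 by at least 16-fold. The median log2 fold change was -2.82 among entries that fell and 1.99 among those that rose. In these counts and medians the lower group was set at a floor of 3 counts over its libraries in the 4 falling entries and 1 rising entry that had fewer. On its fitted value that rising entry, with 1 count in HMLE, would pass 16-fold. Fitted changes of more than 16-fold also occurred in both directions among entries that did not pass. For example, an entry at 134 and 6.33 CPM in HMLE replicates 1 and 5 had a log2 fold change of 4.77 (edgeR adjusted p = 0.0913). Another had -4.70 (edgeR adjusted p = 0.0505). The 72 falling entries held 16.4% and 22.2% of assigned counts in the HMLE libraries and between 4.06% and 5.20% in the mesHMLE libraries. The 31 rising entries held 1.42% and 1.05% in HMLE and between 3.33% and 4.57% in mesHMLE. The calls were selected on these same libraries, so these shares describe their size and are not independent evidence of their direction.

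**Figure D1:**
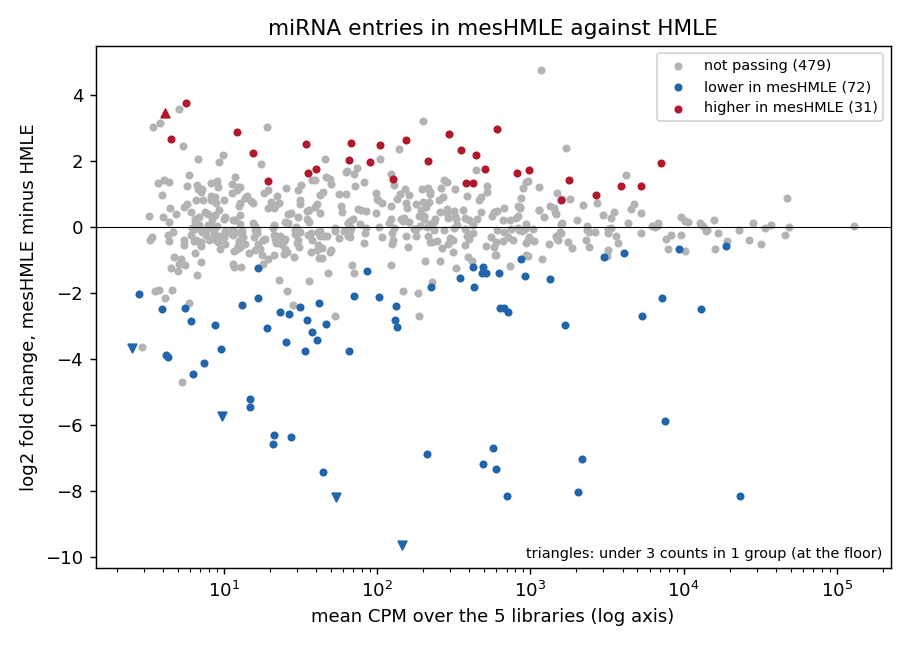
Log2 fold change (mesHMLE minus HMLE, vertical axis) against mean CPM over the 5 libraries (horizontal log axis) for the 582 tested entries, 1 point each. Blue marks the 72 entries lower in mesHMLE, red the 31 higher and grey the 479 that did not pass, and triangles mark entries with fewer than 3 counts over the libraries of 1 group, drawn with that group at 3 counts; the blue points reach far lower than the red points reach up.

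Changes occurred at every level of abundance. Among 101 tested entries with a mean of at least 1000 CPM, 13 fell, 4 of them by at least 16-fold, and 6 rose. Among 304 entries under 100 CPM, 36 fell and 12 rose. Among entries with a mean of at least 1000 CPM, the largest change was that of MIMAT0000266_1, the second most abundant entry in HMLE. It fell from 58051 ± 19650 CPM (SD, n = 2) to 206 ± 92.03 CPM (SD, n = 3), a log2 fold change of -8.14 (SE 0.533, edgeR adjusted p = 0.00508) or 282-fold. MIMAT0009197_1 stood at 134 ± 72.9 CPM in HMLE (SD, n = 2) with 194 and 470 counts, and had 0 counts in every mesHMLE library. Against a floor of 3 counts over the 3 mesHMLE libraries (0.459 CPM), it was at least 293-fold lower (edgeR adjusted p = 0.0176). That bound covers counting error in mesHMLE and not the spread between the HMLE libraries.

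The largest rise among called entries with a mean of at least 10 CPM was that of MIMAT0004592_1, from 119 ± 4.93 CPM (SD, n = 2) to 928 ± 104 CPM (SD, n = 3), a log2 fold change of 2.96 (SE 0.249, edgeR adjusted p = 0.00508) or 7.80-fold. MIMAT0004501_1 rose from 140.2 ± 69.1 CPM (SD, n = 2) to 644 ± 52.4 CPM (SD, n = 3), a log2 fold change of 2.20 (SE 0.40, edgeR adjusted p = 0.027) or 4.59-fold. For each of these 4 entries, every library of one group lay above every library of the other.

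**Figure D2:**
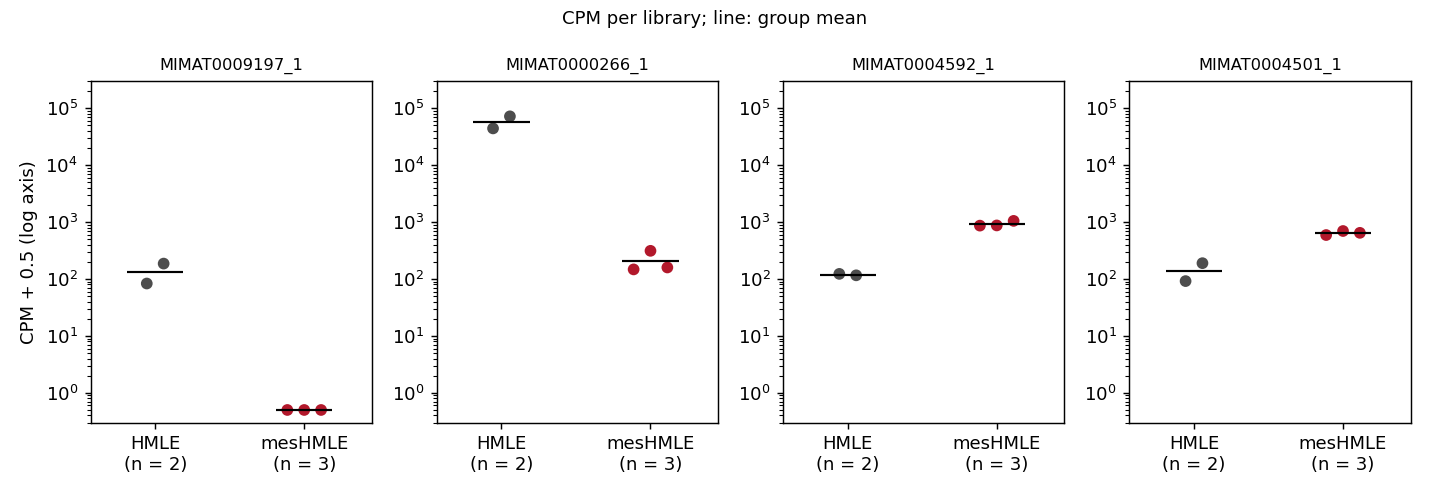
CPM plus 0.5 (vertical log axis) in each library for the 4 entries described, with 2 HMLE libraries in grey, 3 mesHMLE libraries in red and a line at the group mean. MIMAT0000266_1 and MIMAT0009197_1 are lower in every mesHMLE library than in either HMLE library, and MIMAT0004592_1 and MIMAT0004501_1 are higher. The rule that picked these entries required this separation.

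The groups did not overlap for 291 of the 582 tested entries (50%), where chance alone gives 20%. All 103 called entries were among them. The number of calls depended on single libraries. Without HMLE replicate 5, 53 entries passed, without mesHMLE replicate 4, 12 passed, and without mesHMLE replicate 5, 2 passed. Without mesHMLE replicate 3, edgeR called 0 entries, with 137 at an unadjusted p under 0.05, while DESeq2 called 97 on the same 4 libraries. Without mesHMLE replicate 4 or 5, edgeR gave 149 and 146 entries at an unadjusted p under 0.05, against 184 with all libraries. The number of entries at a low unadjusted p thus fell much less than the number of calls. Scaling by library totals alone moved the median log2 fold change of all tested entries from -0.04 to 0.16 and the share of calls that fell from 69.9% to 57.6%.

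Libraries of the same group also differed from each other, above all the 2 HMLE libraries. Over the 582 tested entries, log2 CPM correlated across entries at r = 0.913 between the HMLE libraries and at r = 0.941 to 0.983 between the mesHMLE libraries, where entries are not independent replicates. Of 477 entries with a mean of at least 10 CPM, 73 differed by more than 4-fold between the HMLE libraries. The corresponding numbers in mesHMLE were 0 between replicates 3 and 5, 45 between replicates 3 and 4, and 55 between replicates 4 and 5. By the same measure HMLE replicate 1 differed from mesHMLE replicate 3 in 50 entries, fewer than from HMLE replicate 5, and by a median absolute log2 difference of 0.54 against 0.57. Other measures placed the HMLE libraries closer to each other, with r = 0.898 and a chi-square per degree of freedom of 524 between HMLE replicate 1 and mesHMLE replicate 3, against 0.913 and 390. The other 5 pairs across the groups differed in 74 to 130 entries, with r = 0.779 to 0.890. No pair of libraries differed by so little that it could be 1 library deposited more than once (chi-square per degree of freedom of at least 75.8), which does not show that the libraries came from separate cultures.

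Of the 73 entries that differed between the HMLE libraries, 51 belonged to a set that moved together. Each of these was more than 4-fold lower in HMLE replicate 5 than in HMLE replicate 1 and more than 4-fold lower in mesHMLE replicate 4 than the mean log2 CPM of mesHMLE replicates 3 and 5. Their median level was 215 CPM in HMLE replicate 1 and 15.8 CPM in HMLE replicate 5. In mesHMLE it was 168 CPM in replicate 3, 28.2 CPM in replicate 4 and 392 CPM in replicate 5. The 2 libraries with the low levels also had the highest share of reads under the mapping quality minimum in their group, 39.82% against 36.78% in HMLE and 45.72% against 42.54% and 42.04% in mesHMLE. Across the groups this order did not hold, since mesHMLE replicates 3 and 5 had higher shares than HMLE replicate 5 and also higher levels. The set was defined after the values were seen, and its choice by a wide spread within both groups leaves no fair test of it between the groups.

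**Figure D3:**
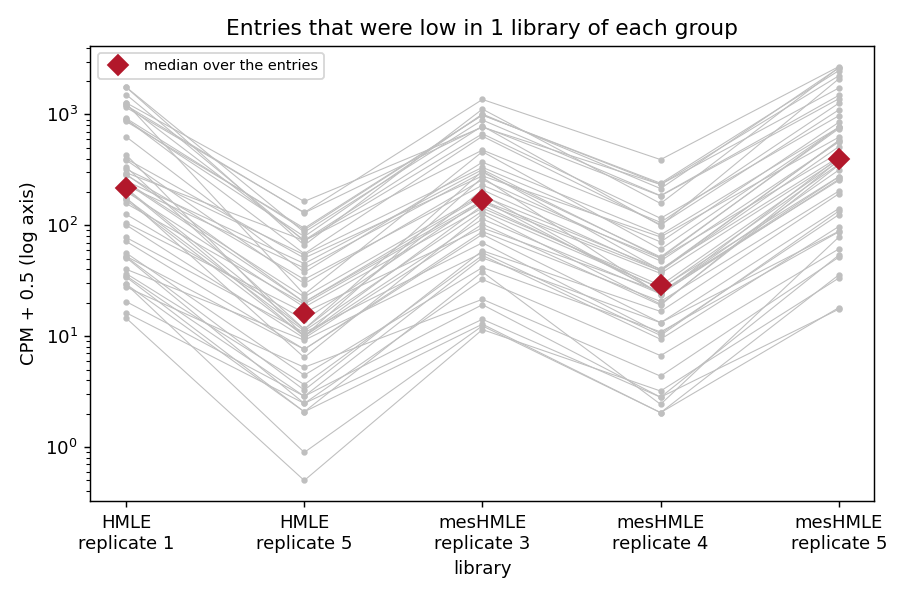
CPM plus 0.5 (vertical log axis) of the 51 entries of this set in each of the 5 libraries (horizontal axis), with a grey line per entry and a red diamond at the median. The median is 15.8 CPM in HMLE replicate 5 and 28.2 CPM in mesHMLE replicate 4, against 168 to 392 CPM in the other 3 libraries.

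The fate of the remaining reads differed between the groups as well. Reads that fell in no miRNA entry made up 37.8% ± 5.46 (SD, n = 2) of the reads in the HMLE files and 19.5% ± 1.36 (SD, n = 3) in the mesHMLE files. Reads assigned to an entry made up 23.9% ± 7.62 in HMLE (SD, n = 2) and 37.1% ± 2.31 in mesHMLE (SD, n = 3). The groups did not overlap in either measure, and each gave the smallest p that an exact two-sided permutation test of 2 against 3 libraries allows (p = 0.1, adjusted p = 0.2), so neither could pass a threshold of 0.05. Both shares are parts of the same total and are not separate results. The HMLE files also held more reads, 8750943 and 14894944, than the mesHMLE files, with 4481577 to 6602211.

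The series concerns the annotation of human miRNAs, and the counts were also set against the order of the accession numbers, which miRBase assigns broadly in order of registration. Entries registered early held nearly all counts. The 526 entries with the lowest numbers (62 to 4284) held 93.7% ± 0.477 of assigned counts in HMLE (SD, n = 2) and 91.0% ± 0.391 in mesHMLE (SD, n = 3), and 69.2% of them had a count in any library. The 526 entries with the highest numbers (19231 to 22839) held 0.150% ± 0.0381 in HMLE (SD, n = 2) and 0.199% ± 0.0318 in mesHMLE (SD, n = 3), although 53.2% of them had a count. Of these late entries, 48 were abundant enough to be tested, of which 6 fell and 1 rose. Of the 269 tested entries among those with the lowest numbers, 36 fell and 7 rose. The Argonaute-bound fraction was not analysed here.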

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

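The result in this part was chosen after the values were seen. Reads set aside for low mapping quality, which enter no comparison of entries, made up a larger part of every mesHMLE file than of either HMLE file: 43.43% ± 1.99 (SD, n = 3) against 38.3% ± 2.15 (SD, n = 2), with p = 0.1 in an exact two-sided permutation test, the smallest it can give. As a share of these reads and the assigned reads together, the order was the opposite, 53.9% ± 2.54 in mesHMLE (SD, n = 3) and 62.0% ± 8.91 in HMLE (SD, n = 2), with overlapping libraries (exact permutation p = 0.2).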

How the results depend on the processing

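The 103 calls, 72 lower and 31 higher in mesHMLE, depended most on which libraries were used. Leaving out 1 library gave 0 to 114 calls, of which 0 to 70 fell and 0 to 44 rose, with the lowest without mesHMLE replicate 3 (edgeR; 137 at an unadjusted p under 0.05, and 97 calls by DESeq2) and the highest without HMLE replicate 1. The difference in the share of the 10 most abundant entries ranged from 1.87 to 4.04 points in the same way and was 0.524 points for 20 entries. A threshold of 0.01 left 12 calls (10 fell, 2 rose), and glmTreat against a log2 fold change of 1 left 43 (36 fell, 7 rose), as both ask for more. With upper quartile scaling 46 entries fell. With DESeq2 67 rose, among 150 calls, of which 99 were shared with the 103. Library totals alone gave 99 calls, 88 of them shared. Chosen after seeing the data, without the 51 co-varying entries 150 passed and 63 rose, and without HMLE replicate 5 and mesHMLE replicate 4 there were 58 calls (43 fell, 15 rose). Other causes were not tested. The 4 printed entries kept their sign under all 19 alternatives. This could hardly come out otherwise, since they were picked for large changes without overlap between the groups. The threshold of 0.01, glmTreat and the fit that was not robust also left their fold changes as they were. MIMAT0000266_1 (log2 fold change -8.57 to -7.74) and MIMAT0004592_1 (2.91 to 3.17) each missed the threshold in 2, with adjusted p of up to 0.0641. MIMAT0009197_1 (fitted, -11.72 to -9.07) missed it in 4 (up to 0.0757) and MIMAT0004501_1 (1.77 to 2.83) in 5 (up to 0.111). No paired analysis was possible because the groups share only 1 replicate number. The preset lists and the arm test were not run under any setting. At this depth a count of 0 in a single library cannot tell absence from a level of up to about 1.09 to 1.69 CPM.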

Other observations

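Apart from the 10 regroupings of the libraries, the tests in this part were chosen after the results were seen. For the 2 checks of the accession band by scaling and abundance, predictions were written beforehand, but the band itself was picked from the results. Entries that rose in mesHMLE were concentrated in a run of accession numbers. Of 145 tested entries numbered from 4000 to under 5000, 18 rose (12.4%), against 3.0% of the other tested entries (odds ratio 4.61, Fisher's exact test, adjusted p = 0.000851 over 16 tests of bands 1000 numbers wide). Entries numbered below 1000 were the opposite, with 3 of 176 rising (odds ratio 0.235, Fisher's exact test, adjusted p = 0.0454). They were compared with all other tested entries, including the first band with 18 of the 31 rises, so the 2 results are not separate. Falling entries were concentrated in numbers from 18000 to under 19000, where 8 of 21 fell (odds ratio 4.76, Fisher's exact test, adjusted p = 0.0161). Entries are not independent of each other, so these p-values are likely too small. With library totals alone the odds ratio of the first band was 3.72 (95% interval 1.87 to 7.45). A change of scaling moves all entries of a library together, and 88 of the 99 calls with library totals were also among the main calls. That check could hardly have lost the pattern, so no conclusion on scaling is drawn from it. The common odds ratio over 4 strata of mean CPM was 4.48 (95% interval 1.98 to 10.4), which argues against abundance as the whole cause. Entries registered together may share a property, such as being the less abundant strand of a hairpin, and this was not tested, since the accessions were not paired with arms.

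The 51 entries that were low in HMLE replicate 5 and in mesHMLE replicate 4 point to a difference between libraries that crosses the groups. Of 477 entries, 64 were more than 4-fold lower in the first of these libraries than in the other HMLE library and 53 were more than 4-fold lower in the second than the mean log2 CPM of the other mesHMLE libraries, and 51 were in both lists, where independent lists would share 7.1 (Fisher's exact test, p = 1.05e-53, entries not being independent). Lower depth is argued against, since both libraries had more assigned counts than the others of their group (ratios 1.08 and 1.22), and so is a library-wide scaling, since in the deposited counts, without scaling, the other 426 entries differed by medians of 0.19 and 0.38 on the log2 scale and the 51 by -3.39 and -2.56. A swap of the 2 libraries between the groups is argued against by the 20 entries that fell most in the other 3 libraries, which were higher in HMLE replicate 5 than in mesHMLE replicate 4 by a median of 6.22 on the log2 scale. The share of reads in no entry was higher in HMLE replicate 5 (41.7%) than in replicate 1 (33.98%), but that of mesHMLE replicate 4 (19.12%) lay between those of the other mesHMLE libraries, which argues against it as the cause in both. The share of reads under the mapping quality minimum was the highest of its group in both libraries (39.82% against 36.78%, and 45.72% against 42.54% and 42.04%), and stays open. Across the groups that order did not hold. Shares in mesHMLE replicates 3 and 5 were above that of HMLE replicate 5, but their median levels were 168 and 392 CPM against 15.8 CPM. A difference between cultures or clones of cells, for example in a group of miRNAs transcribed together, also stays open. So does an unrecorded batch shared by the 2 libraries. No biological explanation was tested. The preset lists, some of which held miRNAs of a genomic cluster, were not run because the accessions were not paired with names, and positions were not used here.

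Accessions with several loci had low and unequal counts. Among accessions numbered below 1000, the median CPM summed over loci was 29.5 for 33 accessions with several loci and 537 for 168 with 1 locus, a ratio of 0.055 (two-sided permutation test on mean log2 values with 100000 resamples, p = 0.0015). Random placement of reads between identical copies is argued against, since in the 14 accessions with 2 loci and at least 500 counts the larger copy held a median of 88.3% of counts (55.1% to 98.9%), and its share varied by at most 7.01 points between libraries. A candidate explanation is that reads matching several loci equally well were set aside for low mapping quality and that only reads with distinguishing bases were counted. Truly lower expression of these miRNAs stays open, and the level of such an accession in these files is uncertain for that reason.

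The 5 libraries can be split into 2 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 103 entries by edgeR, with 184 at an unadjusted p under 0.05. The highest of the other 9 gave 0, with 0 to 66 entries at an unadjusted p under 0.05. Among those 9 the highest unadjusted count, 66, came from the split that sets HMLE replicate 5 and mesHMLE replicate 4 apart. The 51 co-varying entries were defined by low levels in these 2 libraries, so that count is not separate evidence of a difference they share.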
